A study of Canis lupus familiaris with 18 samples.

How the data were processed

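RNA had been extracted with TRIzol from primary osteosarcoma tissue snap frozen at surgery, biopsy or necropsy, per the labels' protocols, and biotin-labelled cRNA was made from 10 µg of total RNA. The labels do not say which tumour came from which kind of procedure, and they give no scan date or batch. One array was run per tumour, in 1 colour. The deposited values are log2 signals for 43035 probe sets, not centred per gene, between 2.03 and 15.09. The submitters' processing notes name MAS5, without a version or a step. The values were close between arrays, with upper quartiles between 8.01 and 8.27, and the summary method and its normalization remain unsettled. Detection calls were not used here, so it is not known which probe sets lay above background.

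From these values, 111 control probe sets were set aside for quality measures. Each deposited value was turned back to a linear signal, 16 was added and log2 was taken again, to damp the noise of dim probe sets. No further normalization between arrays was applied. Probe sets whose mean over all 18 arrays lay below the 40th percentile (6.15) were left out, which left 25754. Gene names came from the platform annotation. Of 42924 probe sets other than controls, 29254 carried 1 gene symbol, 439 carried several and 13231 were not listed and are unnamed here. Gene identifiers of 27690 probe sets were found in the RefSeq gene table of the assembly UU_Cfam_GSD_1.0, used for names only, and no coordinates are given. Only probe sets with a single symbol were named.

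Tumours were grouped by the serum ALP concentration in the labels, with 9 in each of 2 groups. Groups were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. ALPL was tested in the same fit and by an exact two-sided permutation test. For the text, 10 genes per direction were to be named by smallest p where fewer passed, together with ALPL and up to 4 members of smallest p of each list. This rule, the 28 gene lists, the design and the first group of settings below were fixed before the data were examined.

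Gene lists were tested on the 10717 genes with 1 symbol, each by its probe set of highest mean, with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists with at least 5 measured members. The same lists were tested with the correlation estimated per list, with fry, and by exact permutation of the list mean. List calls under any other setting used the preset correlation only. A list score is the mean over its members of each tumour's deviation from the mean of all tumours. Correlations across tumours used 100000 permutations, and exact permutations within groups, and the relations tested, apart from that of ALPL with the GAPDH difference, were chosen after seeing the data. Principal components were taken from the tested probe sets. The quality measures were the array median and spread, 3' against 5' or middle probe sets of GAPDH and actin, and the BioB, BioD and Dap spike-in controls.

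The fit was tested on simulated data with known changes in 25754 probe sets. Of its 144 calls, 6 were false, and with no change added 5.03% of probe sets had an unadjusted p under 0.05 and 0 were called. A list of osteoblast genes raised by 0.5 on the log2 scale was recovered with both correlations. The simulated genes varied independently of each other, so neither correlation setting was tested on genes that vary together.

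Settings fixed beforehand were offsets of 1 and 64, no filter or the 60th percentile, quantile normalization, scaling to the 75th percentile, eBayes without a trend or with robust estimation, array weights, the tissue number as a block, 1 probe set per gene, an estimated correlation, fry, and leaving out each array. Settings chosen after seeing the data were no offset, leaving out increased ALP replicates 3 and 6 or normal ALP replicate 1 and increased ALP replicate 4, the GAPDH or the actin difference as a covariate, and exact permutation of the list mean. No array was duplicated, since the highest correlation between 2 arrays was 0.966 and at most 0.100% of probe sets had equal deposited values. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for correlations and plots.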

Results

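Gene expression was measured in 18 canine primary osteosarcomas, malignant bone tumours in which the tumour cells deposit bone matrix. The dogs were divided by serum alkaline phosphatase (ALP), an enzyme released into blood mainly from bone and liver, into 9 with a normal and 9 with an increased concentration. Each tumour was hybridised to 1 Affymetrix canine array, and no normal tissue was included. Array medians of the deposited log2 values lay between 6.25 and 6.31, and the rank correlation between arrays lay between 0.929 and 0.98. The precision of every comparison was limited by the 9 arrays per group. Differences are increased minus normal ALP, on the scale of log2(signal + 16), which understates the change of dim probe sets.

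The first comparison asked whether tumour mRNA of ALPL, the gene of the tissue-nonspecific alkaline phosphatase found in bone and liver, differed with the serum enzyme. It was not detectably different at either of its probe sets, while it spanned a wide range within each group. At its _s_at probe set, which can share probes with other transcripts, the level was 11.62 ± 1.38 (SD, n = 9) with normal ALP and 11.20 ± 2.36 (SD, n = 9) with increased ALP. The difference was -0.42 ± 0.85 (SE, 95% interval -2.19 to 1.35), with an adjusted p of 0.948 in limma and an exact two-sided permutation p of 0.660. At its _at probe set the levels were 8.46 ± 1.62 and 8.60 ± 1.90 (SD, n = 9 each), a difference of 0.13 ± 0.77 (SE, 95% interval -1.49 to 1.75), with an exact permutation p of 0.873. There the signal spanned 31.8-fold with normal and 25.1-fold with increased ALP. The interval of the _s_at probe set allowed a fold of increased over normal ALP from 0.219 to 2.55. The _s_at signal spanned 32.6-fold among the tumours with normal ALP and 131-fold among those with increased ALP, but 1 tumour widened each range. The range was 5.83-fold without normal ALP replicate 3 and still 31.1-fold without increased ALP replicate 2. Increased ALP replicate 2 was lowest at 6.50, and without it the difference at this probe set was 0.16, while it was -1.19 with array weights. The sign at the _at probe set turned with array weights, at -0.24, and on leaving out any of 6 single arrays, with a lowest value of -0.17.

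**Figure D1:**
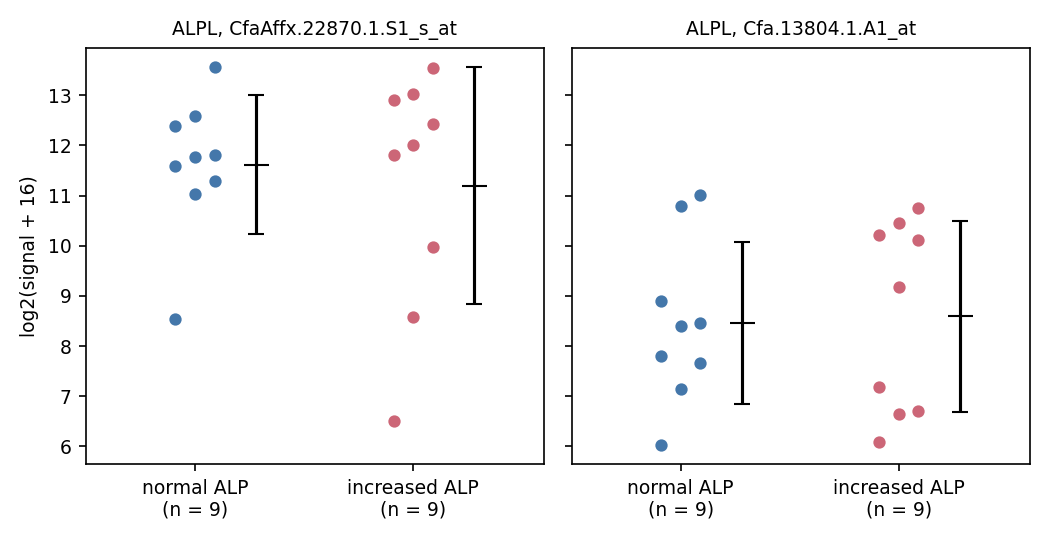
ALPL level as log2(signal + 16) at 2 probe sets in each tumour, with 9 tumours per serum ALP group; points are tumours and bars show the mean ± SD. At the _s_at probe set on the left the tumours with normal ALP lie between 8.54 and 13.57 and those with increased ALP between 6.50 and 13.53.

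Across the transcriptome, no gene could be called different between the groups. The genes of smallest p in each direction are given with their values, and none of them passed. Among those lower with increased ALP were DCUN1D1, a factor in cullin neddylation, at -0.94 ± 0.17 (SE), and RDX (radixin), which links actin filaments to the cell membrane, at -1.09 ± 0.25. PTGES3, a co-chaperone of HSP90, stood at -0.95 ± 0.21, MBNL1, a splicing regulator, at -0.83 ± 0.19, and CPEB4, a translational regulator that binds mRNA, at -0.63 ± 0.14. The others were DENND10 at -0.73, RNF13, a ubiquitin ligase, at -0.72, PPP4R3B, a subunit of protein phosphatase 4, at -0.68, LOC609990 at -0.62 and B3GNT2, which extends glycan chains, at -0.55. At each of these probe sets all 9 tumours with increased ALP lay below the mean of those with normal ALP, which can follow from choosing them by smallest p.

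Among the genes higher with increased ALP were SUPT3H, a subunit of the SAGA transcription complex, at 1.08 ± 0.30 (SE), and EP400, a chromatin remodeller, at 0.69 ± 0.21. AIFM2, an oxidoreductase that protects membranes from lipid peroxidation, stood at 0.63 ± 0.19 and SLIRP, which binds mitochondrial mRNA, at 0.46 ± 0.13. The others were THAP6 at 0.40, PI4KB, a Golgi lipid kinase, at 0.39, FRS3, an adaptor of fibroblast growth factor receptors, at 0.30, GRB10, an adaptor that dampens insulin receptor signalling, at 0.24, MUC2, a gel-forming mucin, at 0.24 and the ribosomal protein gene RPS27 at 0.19. The other MUC2 probe set went the opposite way, as did 1 of the 5 other probe sets of MBNL1. Several of these probe sets end in _s_at or _x_at and can share probes with other transcripts. With the actin 3' to middle difference, a measure of RNA quality that differed between the groups, in the fit, 10 of the 20 named differences shrank by over 1.5 times. EP400 then stood at 0.10, SUPT3H at 0.51 and RNF13 at -0.27, while DCUN1D1 stood at -0.87 and AIFM2 at 0.66. The genes were picked by smallest p in the same arrays, and this covariate correlated with the group at 0.667. The shrinkage was not compared with that of other genes, so it cannot be assigned to RNA quality.

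In limma's moderated test of 25754 probe sets, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.608. At an unadjusted p under 0.05 there were 1582 probe sets, against 1288 given by chance for independent probe sets, of which 494 were higher and 1088 lower. The lower share was thus 68.8%, and it lay between 65.6% and 72.3% without single arrays. It was 54.8% when each array was scaled to a common 75th percentile and 50.6% with no filter on dim probe sets. Without 2 arrays of high spike-in signal it was 63.5%, and with the actin 3' to middle difference in the fit it was 50.3%. With the matching GAPDH difference in the fit, 436 of 686 were lower. In simulated data of the same size and spread, but with independent probe sets, 40.3% of 1.5-fold changes, 76.1% of 2-fold changes and 90.9% of 4-fold changes were called. These shares are averages over probe sets drawn from all those tested, whose median SD within groups was 0.36. They do not apply to more variable genes such as ALPL, with SDs of 1.38 and 2.36 at its _s_at probe set.

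The bone-forming programme was not detectably shifted between the groups. Of 21 measured osteoblast and bone matrix genes, 10 were higher and 11 lower, with a mean shift of 0.01 and a median of -0.03 (adjusted p = 0.853). SERPINF1, a secreted inhibitor of vessel growth, stood at 0.40 ± 0.20 (SE), BMP2, a bone morphogenetic protein, at 0.69 ± 0.35, and PHEX, an endopeptidase of phosphate control, at 0.78 ± 0.61. Of 10 genes of mineral deposition, 3 were higher and 7 lower (mean shift -0.03, adjusted p = 0.755), among them the phosphate transporter SLC20A1 at -0.36 ± 0.22 and GPLD1, a phospholipase that releases membrane-anchored proteins, at -0.20 ± 0.14. Osteoclast genes were lower for 8 of 10 members (mean shift -0.24, adjusted p = 0.132). They were called lower without normal ALP replicate 1, 2 or 3 or increased ALP replicate 4, most at -0.46 without normal ALP replicate 3 (adjusted p = 0.0197), while the shift was -0.051 without increased ALP replicate 7. The osteoclast calls used the preset correlation of 0.01, against 0.616 estimated in the main fit, and were not repeated with an estimated one. OSTM1, a membrane protein required for bone resorption, was lower by a log2 difference of -0.58 ± 0.18 (SE). It was the 1 member of any list to pass when adjusted over the list alone, and 0 members of any list passed over all genes tested.

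Secreted regulators of bone turnover had 8 of 13 members higher (mean shift 0.03, adjusted p = 0.998), with the cytokine TNF at 0.20 ± 0.10 (SE), PTHLH, which encodes parathyroid hormone-related protein, at -0.85 ± 0.48, the receptor OSMR at -0.57 ± 0.34 and TNFSF11, which encodes the osteoclast factor RANKL, at -0.65 ± 0.47. Cartilage genes were split between 7 higher and 8 lower (mean shift -0.15, adjusted p = 0.810). The cartilage proteoglycan ACAN stood at -0.88 ± 0.52 and CNMD, which encodes chondromodulin, at -1.63 ± 0.95. The cartilage list was called lower with the actin 3' to middle difference (shift -0.88, adjusted p = 0.000164) or the matching GAPDH difference (shift -0.52, adjusted p = 0.00944) in the fit, while its shift was -0.0028 without normal ALP replicate 3. Both calls used the preset correlation of 0.01, against 0.182 estimated in the main fit, and were not repeated with an estimated one. Fibroblast and interstitial matrix genes were lower for 16 of 21 members (mean shift -0.17, adjusted p = 0.0813), with the collagen-binding proteoglycan LUM at -0.59 ± 0.25 and COL6A1 at -0.61 ± 0.32. They were called lower without any 1 of 6 arrays, most at -0.30 without increased ALP replicate 7 (adjusted p = 0.00270), and also with 75th percentile scaling (shift -0.13, adjusted p = 0.0369), but the shift was 0.034 with the actin 3' to middle difference in the fit. The fibroblast calls likewise used the preset correlation only, against 0.342 estimated in the main fit. Matrix-degrading enzymes and their inhibitors had 10 of 17 members lower (mean shift -0.13, adjusted p = 0.755), with the urokinase gene PLAU at -0.45 ± 0.31. Their shift was -0.034 without normal ALP replicate 7.

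Markers of non-tumour cells were higher with increased ALP in 4 lists under a preset correlation between genes of 0.01. Of 100 splits of the tumours, the real one included, 84 gave at least as many lists as the 5 called for the ALP groups. Neutrophil genes were higher for 9 of 9 members, with a mean shift of 0.60, or 1.52-fold (adjusted p = 0.00214, but p = 0.0671 and adjusted p = 0.987 with an estimated correlation). Their shift was 0.26 without increased ALP replicates 3 and 6 and -0.072 with the actin 3' to middle difference, which was larger with increased ALP, in the fit. The granule proteins LTF and CAMP stood at 0.89 ± 0.39 (SE) and 0.52 ± 0.31, and the calprotectin subunits S100A8 and S100A9 at 1.36 ± 0.68 and 1.52 ± 0.78. Endothelial genes were higher for 15 of 16 members (mean shift 0.35, adjusted p = 0.00427, but p = 0.250 and adjusted p = 0.987 with an estimated correlation), with the receptors TEK at 0.73 ± 0.40 and ROBO4 at 0.15 ± 0.10. With the actin difference in the fit their shift was 0.49, and with the matching GAPDH difference it was 0.23. Fat cell genes were higher for 9 of 10 members (mean shift 0.52, adjusted p = 0.0270, but p = 0.0835 and adjusted p = 0.987 with an estimated correlation), and their shift was 0.28 with the actin difference in the fit. Among them PPARG, the main regulator of fat cell differentiation, stood at 0.59 ± 0.31 and the fatty acid carrier FABP4 at 1.99 ± 1.07. T and NK cell genes were higher for 13 of 13 members (mean shift 0.18, adjusted p = 0.0272, but p = 0.271 and adjusted p = 0.987 with an estimated correlation), with the kinase LCK at 0.34 ± 0.16 and the receptor CD5 at 0.18 ± 0.09. Their shift was 0.20 with the actin difference in the fit.

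In the other direction, genes of mitochondrial respiration were lower for 18 of 22 members (mean shift -0.11, adjusted p = 0.0270, but p = 0.337 and adjusted p = 0.987 with an estimated correlation). Their shift was -0.064 without increased ALP replicates 3 and 6, -0.042 with the GAPDH and -0.029 with the actin difference in the fit, and -0.065 with 75th percentile scaling, where it was still called (adjusted p = 0.0369). SDHD, a subunit of succinate dehydrogenase, stood at -0.37 ± 0.14 (SE) and NDUFB8, a subunit of complex I, at -0.30 ± 0.17.

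Exact permutation tests of the means of these 5 lists gave p = 0.0468, 0.281, 0.119, 0.361 and 0.350 in the order given, with a smallest adjusted value of 0.976 over the 25 lists tested, and the rotation test fry called 0 lists. Without increased ALP replicates 3 and 6, or with the actin difference in the fit, endothelial genes alone were called higher and respiration genes were not called, and neither was called with the GAPDH difference in the fit. With that difference the neutrophil shift was 0.40 and the fat cell shift 0.45 (adjusted p = 0.0666 each), and the T and NK cell shift was 0.16 (adjusted p = 0.0945). Without these 2 arrays the fat cell shift was still 0.46 (adjusted p = 0.0857) and the T and NK cell shift 0.17 (adjusted p = 0.0857). The neutrophil call held on leaving out each of the 18 arrays, but the shift was 0.40 without increased ALP replicate 3. The respiration call was lost without any 1 of 7 arrays, namely normal ALP replicates 2, 5, 6 and 9 and increased ALP replicates 2, 3 and 7, with an adjusted p of up to 0.292. The shift was -0.063 without normal ALP replicate 6 and -0.067 without normal ALP replicate 9 or increased ALP replicate 3. The T and NK cell call was lost without any 1 of 8, namely normal ALP replicates 3, 4, 6, 7 and 8 and increased ALP replicates 2, 6 and 8 (adjusted p up to 0.353). Its shift was 0.11 without increased ALP replicate 2, 0.071 without increased ALP replicate 8 and 0.27 without normal ALP replicate 2, and the call was also lost with no filter on dim probe sets, at a shift still of 0.18 (adjusted p = 0.0534). With the filter at the 60th percentile the neutrophil and T and NK cell lists kept 2 and 4 members and were not tested, and the calls of fat cell and respiration genes were lost at shifts of 0.62 and -0.11 (adjusted p = 0.0542 each). The endothelial call was lost without normal ALP replicate 2 or 7 or increased ALP replicate 1 or 2 (adjusted p up to 0.0820), with a shift of 0.21 without normal ALP replicate 2 and of 0.23 without normal ALP replicate 7 or increased ALP replicate 1. The fat cell call was lost without normal ALP replicate 2 or increased ALP replicate 1 or 2 (adjusted p up to 0.235).

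**Figure D2:**
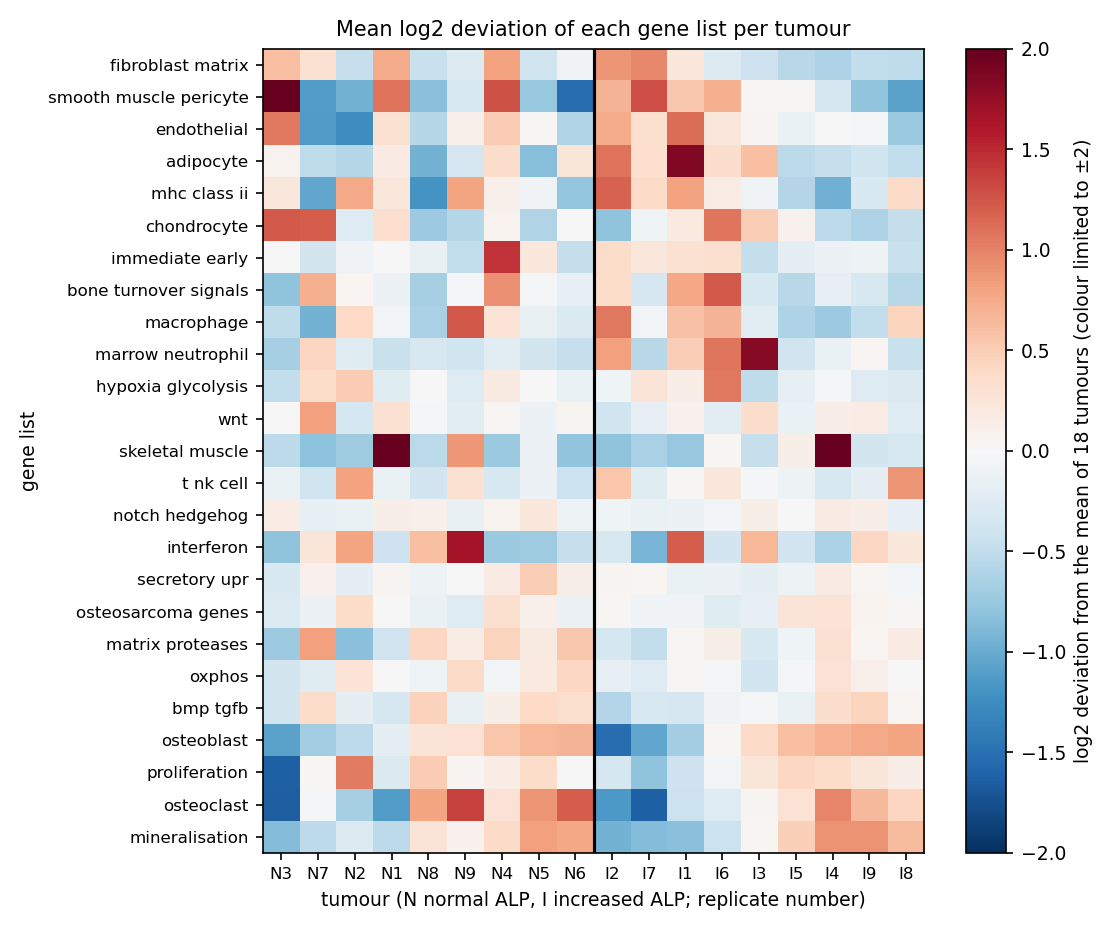
Mean log2 deviation of the measured members of each gene list from the mean of 18 tumours, per tumour, with tumours ordered within each serum ALP group by their osteoblast genes and colours limited to ±2. The osteoblast score runs from -1.06 to 0.69 with normal ALP and from -1.52 to 0.79 with increased ALP, and 1 tumour of each group stands far above the rest for skeletal muscle genes, at 4.04 and 2.54.

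The other cell types were not called. Macrophage genes were higher for 14 of 17 members (mean shift 0.15, adjusted p = 0.373), with LYZ at 0.62 ± 0.31 (SE), and genes of antigen presentation on MHC class II for 7 of 9 (mean shift 0.21, adjusted p = 0.373), with CD74 at 0.50 ± 0.47. The macrophage list was called higher without normal ALP replicate 9 (shift 0.30, adjusted p = 0.0155), and the MHC class II list without the 2 tumours of highest skeletal muscle genes (shift 0.39, adjusted p = 0.0418). The macrophage shift was 0.023 without increased ALP replicate 2, and the MHC class II shift 0.077 without normal ALP replicate 8. Both calls used the preset correlation only, against 0.577 and 0.718 estimated in the main fit. Smooth muscle and pericyte genes were higher for 6 of 8 members (mean shift 0.24, adjusted p = 0.731), with ACTA2 at 0.79 ± 0.52, but the shift was -0.031 with array weights and -0.11 with the GAPDH difference in the fit. It ranged from 0.068 without normal ALP replicate 6 to 0.51 without normal ALP replicate 3. Skeletal muscle genes were lower for 10 of 13 members (mean shift -0.15, adjusted p = 0.764), but the direction of the mean rested on 1 tumour. Their shift was 0.33 without normal ALP replicate 1, -0.45 without increased ALP replicate 4 and 0.068 without both, and with array weights they were called lower (shift -0.73, adjusted p = 0.00877). That call used the preset correlation only, against 0.671 estimated in the main fit. Epithelial, B and plasma cell, and red cell precursor genes had fewer than 5 measured members and were not tested. Their members of smallest p stood at 0.24 ± 0.17 for KRT18, 0.05 ± 0.09 for POU2AF1 and 0.09 ± 0.10 for SPTB.

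Cell division genes were split between 11 higher and 15 lower (mean shift -0.05, adjusted p = 0.755), with MCM3 at -0.45 ± 0.29 (SE) and BIRC5 at 0.33 ± 0.26. They were called lower without normal ALP replicate 3, at a shift of -0.26 (adjusted p = 0.000504), and the shift was above 0 without any 1 of 3 other arrays, at up to 0.077. That call used the preset correlation of 0.01, against 0.729 estimated in the main fit, and was not repeated with an estimated one. Interferon response genes were lower for 11 of 17 members (mean shift -0.03, adjusted p = 0.897), and immediate early genes were higher for 10 of 16 (mean shift -0.02, median 0.03, adjusted p = 0.918). Genes of BMP and TGF-beta signalling were lower for 14 of 21 members (mean shift -0.14, adjusted p = 0.373), with TGFB2 at -0.83 ± 0.37 and SMAD9 at -0.55 ± 0.26. Wnt signalling genes were lower for 12 of 22 (mean shift -0.10, adjusted p = 0.853), with the Wnt antagonist SFRP4 at -1.46 ± 0.79, and Notch and Hedgehog genes for 4 of 9 (mean shift -0.03, median 0.02, adjusted p = 0.897). The Wnt shift was -0.0057 without normal ALP replicate 7. Hypoxia and glycolysis genes had 9 of 20 members higher (adjusted p = 0.853), with PDK1 at 0.48 ± 0.22 and GPI at -0.33 ± 0.14. Genes of the secretory pathway were lower for 13 of 21 (mean shift -0.07, adjusted p = 0.341), with DNAJB9, an endoplasmic reticulum co-chaperone, at -0.60 ± 0.27. They were called lower without normal ALP replicate 3 (shift -0.11, adjusted p = 0.0421) and with array weights (shift -0.10, adjusted p = 0.0171). The secretory shift was -0.013 without normal ALP replicate 5, and -0.0071 with the GAPDH and 0.061 with the actin difference in the fit. Both calls used the preset correlation only, against 0.250 estimated in the main fit. Genes often studied in osteosarcoma were split 8 to 8 (adjusted p = 0.897), with CDK4 at -0.25 ± 0.12 and IGF1R at 0.48 ± 0.29. The test pointed down and the mean up, at 0.02 each, for the hypoxia and the osteosarcoma lists, whose medians were -0.04 and -0.01. The hypoxia mean was -0.11 without increased ALP replicate 6 and also below 0 without any 1 of 4 other arrays. With the actin difference in the fit interferon genes (shift -0.65, adjusted p = 2.9e-05) and Wnt genes (shift -0.37, adjusted p = 0.0133) were called lower. These 2 calls used the preset correlation of 0.01 and were not repeated with an estimated one. The correlations estimated in the main fit were 0.661 for interferon and 0.066 for Wnt genes. Of the 20 lists not called, the sign of the shift turned for 9 on leaving out a single array, among them those of osteoblast genes (from -0.13 to 0.20), mineral deposition (from -0.15 to 0.084), bone turnover regulators (from -0.12 to 0.15), interferon response (from -0.19 to 0.17) and immediate early genes (from -0.084 to 0.17).

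RNA quality moved with the serum ALP group. The difference between the 3' and middle probe sets of actin, which grows as RNA is degraded, was 1.39 ± 0.17 (SD, n = 9) with normal and 1.79 ± 0.29 (SD, n = 9) with increased ALP (exact permutation p = 0.00313, adjusted over 7 measures p = 0.0219). Without increased ALP replicates 3 and 6 the second mean was 1.69 ± 0.24 (SD, exact permutation p = 0.0116). The matching GAPDH difference was 0.74 ± 0.13 and 0.95 ± 0.30 (exact permutation p = 0.0705, adjusted p = 0.196). Across the 18 tumours the neutrophil score correlated with the actin difference at Pearson's r = 0.740 (permutation p = 0.00068, adjusted over 11 relations p = 0.0015) and Spearman's rho = 0.629 (permutation p = 0.00655, adjusted p = 0.0144). Within the groups r was 0.672 with normal ALP (exact permutation p = 0.102) and 0.659 with increased ALP (exact permutation p = 0.0542), and it was 0.490 without increased ALP replicates 3 and 6. These 2 arrays had the highest signal of the BioB spike-in, at 10.29 and 9.81 against at most 9.20 elsewhere. With the Dap spike-in the neutrophil score correlated at r = 0.685 (permutation p = 0.00339, adjusted p = 0.0062). There rho was 0.236 (permutation p = 0.34), and r was 0.193 without these 2 arrays. Within the groups r was -0.448 with normal and 0.875 with increased ALP.

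**Figure D3:**
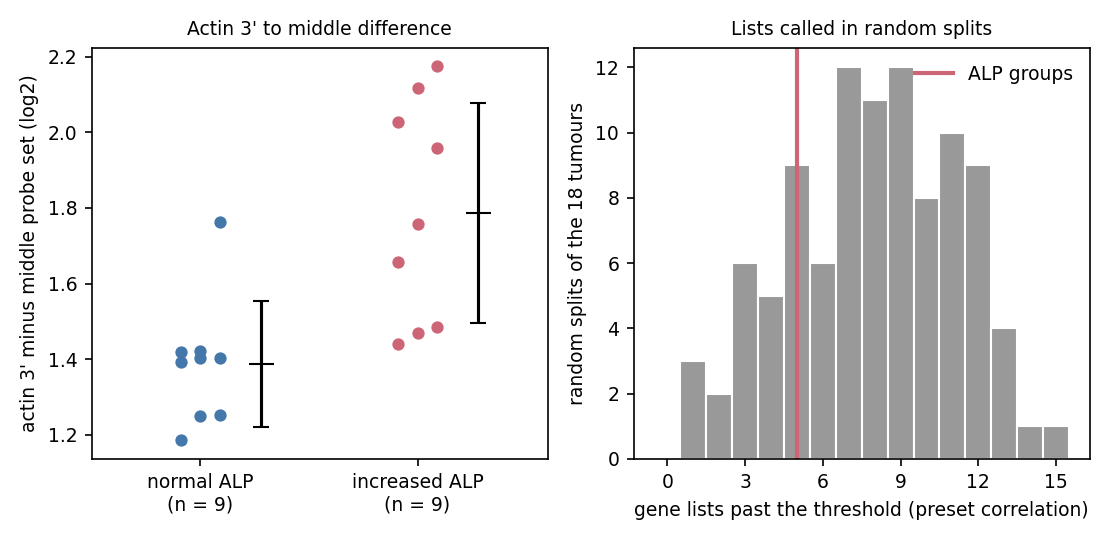
Left, the actin 3' minus middle difference in log2 units for each tumour, with 9 tumours per serum ALP group and bars for the mean ± SD. Right, the number of gene lists past the threshold with a preset correlation when the 18 tumours were split at random, with a line at the 5 lists of the ALP groups and a highest random value of 15.

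The main axes of variation did not separate the groups detectably. The first 3 principal components held 25.2%, 11.4% and 9.47% of the variance, and exact permutation tests of their scores between the groups gave p = 0.685, 0.159 and 0.124. The smallest value adjusted over the 3 components was 0.239.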

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

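A single tumour's distance from the rest of its group was measured as the gap to its nearest neighbour over the range of the group, in 114 sets of 9 values. In 9 sets the ratio exceeded the 95% critical value of Dixon, where chance gives about 5.7, or about 1 in 20. The values are given without an explanation.

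Skeletal muscle genes were far above the rest in 1 tumour of each group. The score was 4.04 in normal ALP replicate 1, against 0.87 in the next tumour (ratio 0.653), and 2.54 in increased ALP replicate 4, against 0.11 (ratio 0.728). Normal ALP replicate 7 had a neutrophil score of 0.43, the next being -0.23 (ratio 0.605), and also an actin 3' to middle difference of 1.76, the next being 1.42 (ratio 0.592). Normal ALP replicate 3 was lowest in its group for cell division genes, at -1.64 with the next at -0.29 (ratio 0.505), and for ALPL at its _s_at probe set, at 8.54 with the next at 11.03 (ratio 0.494). Normal ALP replicate 4 had an immediate early gene score of 1.44 with the next at 0.21 (ratio 0.636). Increased ALP replicate 6 had a hypoxia and glycolysis score of 1.05 with the next at 0.26 (ratio 0.503), and increased ALP replicate 3 had an RPS27 level of 14.09 with the next at 13.87 (ratio 0.518).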

How the results depend on the processing

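The count of 0 probe sets past the adjusted threshold held under 16 alternatives and on leaving out each of the 18 arrays, as did the absence of a group difference in the 3 principal components under the alternatives run for them. All 652 values of the named genes under alternatives kept their direction and 0 passed, with a lowest adjusted p of 0.0684 for RDX. The kept direction says little, since these genes were picked by smallest p in the same arrays. The actin covariate correlated with the group at 0.667. With it 10 of the 20 genes shrank by over 1.5 times, EP400 most, to 0.10. Covariates, no offset, the arrays left out in pairs and permutation of list means were chosen after seeing the data. Probe sets at an unadjusted p under 0.05 numbered 2625 with no filter, 976 with the 60th percentile and 533 with 1 probe set per gene, where more or fewer were tested. They numbered 850 without increased ALP replicates 3 and 6, 686 with the GAPDH and 772 with the actin covariate, and 1156 to 2246 without single arrays. Their lower share was 50.63% with no filter, 54.75% with 75th percentile scaling and 50.26% with the actin covariate. With the GAPDH covariate 436 of the 686 were lower. The _at probe set of ALPL turned to -0.24 with array weights and to -0.24 without the 2 tumours of high muscle genes. Without single arrays it ranged from -0.17 to 0.45, at -0.03 and -0.17 without normal ALP replicates 2 and 3 and at -0.06, -0.14, -0.10 and -0.07 without increased ALP replicates 3, 4, 8 and 9. The _s_at probe set of ALPL was -1.19 with array weights, -0.75 without increased ALP replicates 3 and 6, -0.76 without the tumours of high muscle genes and -0.82 with the actin covariate. Without single arrays it ranged from -0.81 to 0.16, above 0 only without increased ALP replicate 2. Of 4 lists higher, 1 was left with the 60th percentile (neutrophil and T and NK cell genes had too few members to be tested, and the fat cell shift was 0.62 with an adjusted p of 0.0542), 0 with an estimated correlation, 0 with fry, 0 by exact permutation, 1 without increased ALP replicates 3 and 6, 0 with the GAPDH and 1 with the actin covariate. Without single arrays 1 to 5 were higher, namely 2 without normal ALP replicate 2 or 7 or increased ALP replicate 1, and 1 without increased ALP replicate 2. Against 1 list lower (respiration), 2 were lower with no filter, quantile normalization or 75th percentile scaling (fibroblast too), 5 with array weights (respiration, fibroblast, osteoclast, skeletal muscle and secretory genes), 0 with the 60th percentile (respiration shift unchanged, adjusted p = 0.0542), 0 with an estimated correlation, fry or exact permutation, 0 without increased ALP replicates 3 and 6, and 2 without the tumours of high muscle genes (osteoclast too). Respiration genes were not among the lists lower with the actin covariate, which were 3 (cartilage, interferon and Wnt genes), nor with the GAPDH covariate, where cartilage genes were the 1 list. Without single arrays 0 to 4 were lower, namely 0 without normal ALP replicate 6 or increased ALP replicate 3, 4 without normal ALP replicate 3 (respiration, osteoclast, cell division and secretory genes), and 2 without normal ALP replicate 1, 2 or 8 or increased ALP replicate 4 (osteoclast genes in all but normal ALP replicate 8), and fibroblast genes took the place of respiration genes without normal ALP replicate 5 or 9 or increased ALP replicate 2 or 7. The neutrophil shift turned to -0.072 with the actin covariate. Where not given, the cause was not tested. Equal tissue numbers did not pair the tumours: deviations of same-numbered arrays correlated at -0.16 to 0.27, 4 of 9 pairs exceeded 0.1 and 0 arrays correlated best with their own number. With the number as a block, 4 lists were higher and 1 lower. Without detection calls, signal over background limits what dim probe sets can show.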

Other observations

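The correlations of ALPL and of the neutrophil score, apart from that of ALPL with the GAPDH difference, and the neutrophil shift without 2 arrays were chosen only after the results were seen, as were the settings that leave out those arrays or add a covariate.

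Tumours rich in ALPL mRNA were rich in osteoblast transcripts in both serum groups. Over the 18 tumours ALPL at its _s_at probe set correlated with the osteoblast list without ALPL at Pearson's r = 0.875 (permutation p = 2e-05) and Spearman's rho = 0.884 (permutation p = 1e-05, the smallest that 100000 permutations can give), with adjusted p of 7.33e-05 and 3.67e-05 over a family of 11 relations. It was 0.836 within the normal group (exact permutation p = 0.000408), 0.914 within the increased group (exact permutation p = 0.00193) and 0.828 without the 2 tumours farthest from the median. Both ALPL probe sets correlated with each other at r = 0.857 and rho = 0.938 (permutation p = 1e-05 each, adjusted p = 5.5e-05 and 3.67e-05), and at r = 0.818 without 2 tumours.

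Osteoclast and cell division genes also followed ALPL. With the osteoclast list r was 0.741 (permutation p = 0.00038, adjusted p = 0.00104) and rho 0.768 (permutation p = 0.00035, adjusted p = 0.000963), and r was 0.685 without 2 tumours. Within the groups it was 0.787 with normal ALP (exact permutation p = 0.00504) and 0.793 with increased ALP (exact permutation p = 0.0122). With the cell division list r was 0.616 (permutation p = 0.0096, adjusted p = 0.0151) and rho 0.598 (permutation p = 0.0101, adjusted p = 0.0184), and r was 0.713 without 2 tumours. Within the groups it was 0.674 (exact permutation p = 0.082) and 0.749 (exact permutation p = 0.0187). Smooth muscle genes went the other way at r = -0.547 (permutation p = 0.0178, adjusted p = 0.0245), but rho was -0.439 (permutation p = 0.0697, adjusted p = 0.110). For these genes r was -0.398 without normal ALP replicate 3 and increased ALP replicate 7, -0.588 within the normal group (exact permutation p = 0.0883) and -0.637 within the increased group (exact permutation p = 0.0667).

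The range of ALPL within each group, 31.1-fold with increased ALP and 5.83-fold with normal ALP even without the lowest tumour of each, was set against RNA quality and tissue make-up, although it is not known whether the lowest signals lay above background. RNA degradation measured by actin stayed open, since r with ALPL was 0.0142 over all tumours but -0.307 within the normal group (95% interval -0.807 to 0.449) and 0.267 within the increased group (-0.483 to 0.791). The GAPDH measure also left it open, at r = -0.0808 over all tumours, -0.600 within the normal group (exact permutation p = 0.0941) and 0.108 within the increased group (exact permutation p = 0.773). A candidate explanation is the share of osteoblast-like tissue in each piece, which the correlation of 0.875 is consistent with. That list without ALPL has 20 measured genes, 7 of which also belong to another list, and tumour cells and normal bone cells cannot be separated by it, so a difference between the tumours' own cells stays open.

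More of the probe sets at an unadjusted p under 0.05 were lower than higher, and RNA quality may account for part of this. Chance could not be excluded for their number, since 23 of 100 splits of the tumours, the real one included, gave at least 1582, the highest other split giving 5122, which points to a structure of the samples apart from serum ALP. An excess of one direction as large as 594 came in 2 of the 100, the real grouping being 1 of them, with 914 as the highest other. Chance was thus unlikely for it but not excluded. The splits were run under this processing only. In 16 alternatives the lower share ran from 50.3% to 75.4%, and 13 of them were counted as unchanged. It was 54.8% with 75th percentile scaling, 50.6% with no filter and 50.3% with the actin covariate. Within groups the lower probe sets correlated negatively with the BioB control (median r = -0.365), the actin difference (-0.408) and the GAPDH difference (-0.317). The higher probe sets correlated positively, at 0.314, 0.271 and 0.349, so these correlations alone do not account for an excess of one direction. For BioB and actin the correlation of the lower probe sets lay mostly in the increased group (-0.491 and -0.569, against -0.149 and -0.173 in the normal group). For GAPDH it was -0.379 in the increased and -0.323 in the normal group. Without increased ALP replicates 3 and 6 the BioB, actin and GAPDH medians were -0.180, -0.280 and -0.085. With the actin covariate 388 were lower, against 644 by chance in 1 direction for independent probe sets. The other splits gave a median of 1037 in both directions together, so a count below 644 cannot tell RNA quality from chance. With the GAPDH covariate 436 of 686 were lower. The actin covariate itself correlated with the group at 0.667, so the fit also removes part of any serum ALP effect, which stays open. The lower share of 63.5% without increased ALP replicates 3 and 6 lay between the bounds set for and against these arrays.

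The neutrophil list was higher with increased ALP under the preset correlation but not with an estimated correlation (adjusted p = 0.987), and this could reflect granulocytes in the tissue, and 0 of its 9 measured genes were in another list. For 6 of the 9 the mean with increased ALP lay between 6.38 and 6.72, close to the filter at 6.15, and the normal means of LTF and CTSG, at 5.78 and 6.12, lay below it. Without increased ALP replicates 3 and 6 its shift was 0.258, or 42.8% of the full value, and with the actin covariate it was -0.072, so much of it rested on arrays that also stood apart in quality. More blood or marrow cells of every kind could not be told apart from this, because the correlation with macrophage genes was 0.185 with an interval from -0.309 to 0.600.

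Chance was not excluded for the number of lists, since 84 of 100 splits, the real one included, gave at least the 5 lists called with the preset correlation, the highest other giving 15. The median of the other splits was 8 lists. The 0 probe sets past the adjusted threshold could not be tested in this way, since a count of 0 is reached by any split (100 of 100), and the highest other gave 1.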
